A study of Homo sapiens with 12 samples.

How the data were processed

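RNA was measured in H9-derived NCC and early SMC after 4 passages, each with 0.001% DMSO or 10 µM Nutlin-3a for 8 hours, with 3 libraries per group and 12 in all. The NCC medium held FGF and EGF at 20 ng/ml, CHIR-99021 at 3 µM and BMP2 at 50 pg/ml. Per the labels' protocols, RNA was extracted with Trizol and polyadenylated RNA was sequenced.

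The authors deposited a table of raw counts per gene, 58395 genes by 12 columns, made with HISAT2 2.0.4, HTSeq 0.6.1 and the GRCh38 assembly, per the submitters' processing notes. Those notes state neither the annotation nor the strand setting of the counting, so reads of overlapping genes, antisense genes and close paralogs cannot be assigned with certainty. The authors also deposited a table per comparison made with DESeq2 1.14.1, per the submitters' processing notes. Per the file headers each holds a signal per gene, the mean of the size-factor-normalized counts over all libraries. Per the file headers it also holds a log2 fold change with its standard error, as computed by the authors. The p-value and adjusted p-value columns are, per the file headers, those of the authors' DESeq2 test. The model and the filters are not stated. Those tables were used only as a check. A DESeq2 1.42.0 run here on all 12 libraries gave log2 changes with an r of 1.0000, 0.99998 and 1.0000 across genes with the authors' values for NCC, SMC and the cell types. The authors' adjusted p-values under 0.05 were 588 higher and 374 lower, 220 and 53, and 4465 and 3771. Of the edgeR calls reported here, 634 of 636, 165 of 165 and 7751 of 8284 were among them.

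Gene positions, types and exon overlaps came from GENCODE 29, which holds 58275 of the 58395 gene IDs and 17894 of the 17915 tested. A symbol shared with another ID occurred in 1690 cases, so all joins used IDs. Of 371 genes that the rule below named, 35 had at least 10% of their exon length under genes of the opposite strand and 11 under genes of the same strand. No genome sequence was used here.

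The main test was the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on all 12 libraries with 1 mean per group. It used filterByExpr with a minimum count of 10, which kept 17915 genes, and TMM factors, which ran from 0.887 to 1.12. Residual degrees of freedom were 8, prior degrees of freedom 4.65 and the common dispersion 0.0448. Contrasts were Nutlin-3a against DMSO in NCC, the same in SMC, SMC against NCC with DMSO, and the difference between the drug responses, SMC minus NCC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 change is that of the fitted contrast. CPM values are means ± SD over 3 libraries, computed with TMM-scaled library sizes.

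Gene lists, 39 with 782 members, were written from textbook knowledge before the data were examined. They were tested with camera of limma on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 39 lists, and again with a correlation estimated per list. The estimated correlation of a list comes from 8 residual degrees of freedom. "Adjusted over the list alone" means a Benjamini-Hochberg correction of the edgeR p-values over the measured members of 1 list.

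The named genes followed a rule: *MDM2* and *CDKN1A*, the 10 called genes with the largest change in each direction, and the 4 measured members of each list with the smallest p. The called genes had to reach a mean of 5 CPM in the higher group. Their CPM ranges could not overlap between the groups. Clone names starting with AC, AL, AP or RP, LOC names and Ensembl IDs were left out. The clone name *FP236383.1* has none of these forms and stayed. For the difference the limit was 5 per direction. Part of the genes the rule allows is not reported here. For genes with few counts in a group, the ratio of pooled counts is given with an exact 95% interval that covers counting error only. For genes with no counts in a group a floor is given, with 3 counts over the group as the 95% bound, which also covers counting error only.

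Alternatives were RLE size factors, no filter on low counts, DESeq2, limma-voom, a fit of only the 2 groups compared, each library left out in turn and a replicate block. The fit without a filter estimates the spread over 45125 genes, many with few counts. It adds no counts to a named gene, so a smaller adjusted p there is not stronger evidence. The count columns carry letters that no label ties to the replicate numbers, so the block by number could not be fitted and the letter took its place, a choice made after the data were seen. Whether letters pair the libraries was checked before the fits' calls were compared. Deviations from the group mean of same-letter libraries had correlations across genes of 0.110, 0.490 and 0.532 between the NCC groups, 0.348, 0.536 and 0.444 between the SMC groups, and 0.114, 0.155 and 0.175 between the DMSO groups. Each of the 12 libraries had its best match under its own letter. On this data-based ground letters were treated as pairs in the blocked alternatives and in values given within letters. The main test has no block, so its counts, SEs and p-values are unpaired. A blocked value stands beside a result where it changes a call or moves a count by more than 1.5 times.

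The pipeline was tested on simulated counts with the dispersion and depth of the data, with 200 genes changed per comparison, spread over changes of 1.5, 2 and 4-fold. Of those that passed the filter, at each fold in this order, it called 10.8%, 38.5% and 75.0% for NCC, 10.3%, 41.3% and 81.5% for SMC, 3.23%, 40.0% and 77.3% for the cell types, and 0%, 10.6% and 68.2% for the difference. Unchanged genes were called in 6 of 17487, 5 of 17485, 2 of 17330 and 3 of 17496 cases, and no changed gene was called in the wrong direction. Genes were drawn independently, so false calls in the data may be more frequent. The simulation also had no effect of the replicate letter. Each group holds every letter once, so such an effect would rather widen the spread of the unpaired fit. With the letter as a block, NCC calls were 685 higher and 659 lower, against 442 and 194 without it. Between the cell types 8284 genes were called in the data, far more than the 200 changed here. The simulated shares for that comparison therefore do not carry over to it. Averaged over genes, counting error was the smaller part of the spread, which need not hold for genes with few counts. Between pairs of libraries of 1 group, the chi-square per gene over genes with a summed count of at least 20 was 9.35 to 85.6, where counting error alone gives 1, and log2 CPM correlated with r of 0.963 to 0.988 across genes. Mitochondrial transcripts held 3.52% to 6.09% of the counts and the 10 most abundant genes 5.49% to 7.87%.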

Results

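H9 human embryonic stem cells were turned into cranial neural crest cells (NCC), the migratory embryonic cells that form much of the skeleton, connective tissue and vessel wall of the head. Part of these cells was then moved for 2 days into medium with 10% fetal bovine serum, which starts their differentiation into early smooth muscle cells (SMC). The rest stayed in a medium with FGF, EGF, BMP2 and CHIR-99021, an activator of Wnt signalling. Each cell type received for 8 hours either 10 µM Nutlin-3a, a small molecule that keeps MDM2 from binding p53 and so stabilises p53, or its solvent DMSO at 0.001%. Polyadenylated RNA was sequenced from 3 libraries in each of the 4 groups, named here replicates a, b and c. Total counts per library were 15709578, 20334932 and 16169003 in NCC with DMSO, and 13801350, 17301893 and 16283221 in NCC with Nutlin-3a. They were 22227280, 14557364 and 17311577 in SMC with DMSO, and 22721657, 17031032 and 18282803 in SMC with Nutlin-3a. The first principal component held 69.2% of the variance and separated the cell types. Replicate a of NCC with Nutlin-3a had counts in 38913 genes, against 24456 to 28325 in each of the other 11 libraries.

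The first comparison asked what stabilised p53 changed in NCC. *CDKN1A*, which encodes the cell-cycle inhibitor p21 (ENSG00000124762; GRCh38 chromosome 6, 36676460 to 36687339), rose from 181 ± 113 to 1226 ± 198 CPM, its share of a library's counts (mean ± SD, n = 3). Its log2 change was 2.76 ± 0.40 (SE, n = 3 per group), with an edgeR quasi-likelihood adjusted p of 0.00200. *MDM2*, a p53 target whose product marks p53 for degradation (ENSG00000135679; chromosome 12, 68808176 to 68850686), rose by 3.09 ± 0.33 on the log2 scale, from 205 ± 93.0 to 1742 ± 512 CPM (adjusted p = 1.98e-04). Across the transcriptome 442 of 17915 genes rose and 194 fell, of which 353 and 28 changed by more than 2-fold.

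**Figure D1:**
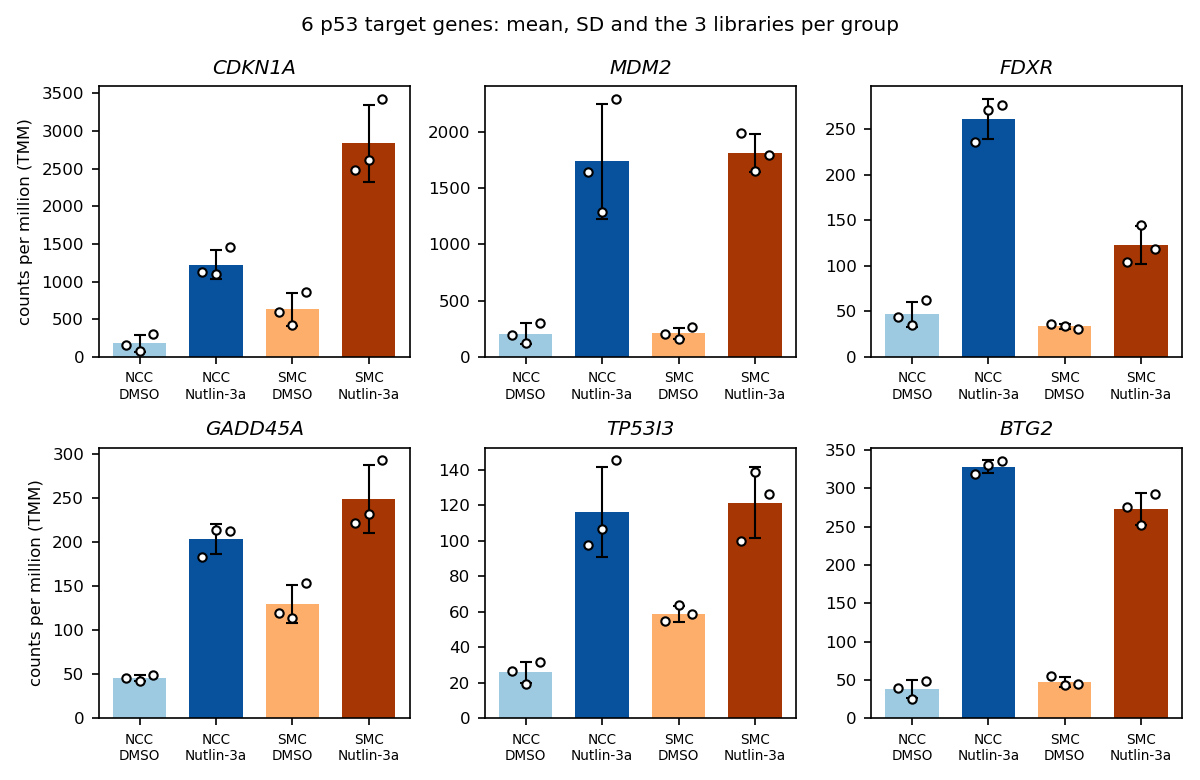
Expression of 6 p53 target genes in the 4 groups, in CPM after TMM scaling. Bars show the mean, error bars the SD and points the 3 libraries of each group. *CDKN1A* and *MDM2* were higher in every Nutlin-3a library than in every DMSO library of the same cell type, and *GADD45A* and *TP53I3* began from a higher level in SMC than in NCC.

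Genes known to be bound and switched on by p53 rose as groups in NCC. Of the 14 measured targets in cell-cycle arrest, 13 rose over all genes and over the list alone (camera adjusted p = 1.42e-24). Examples were the antiproliferative gene *BTG2* (log2 change 3.11 ± 0.20) and *GADD45A*, a stress-induced regulator of repair and of the G2/M transition (2.16 ± 0.15). The sestrins *SESN1* (2.17 ± 0.17) and *SESN2* (1.60 ± 0.13), which restrain mTORC1 signalling, rose with them. Of 18 targets in cell death 15 rose, 17 when adjusted over the list alone (camera adjusted p = 2.82e-25). They included *PIDD1*, part of the caspase-2 activating complex (2.40 ± 0.27), the oxidoreductase gene *TP53I3* (2.17 ± 0.20), and the BH3-only genes *BBC3* (1.62 ± 0.16) and *PMAIP1* (1.36 ± 0.15). Metabolic and redox targets rose in 11 of 17 cases, with 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.78e-16), among them the mitochondrial ferredoxin reductase gene *FDXR* (2.48 ± 0.20). These 3 lists kept their call with an estimated correlation (adjusted p = 0.0282, 0.0282 and 0.0109, in the order given), and lost it with the replicate block added (0.0842 each). Among 10 targets that feed back on p53, 4 rose and 7 rose when adjusted over the list alone, including *TP53INP1* (1.91 ± 0.20) and the phosphatase gene *PPM1D* (1.30 ± 0.15). Among 10 DNA repair targets 5 rose, with 6 higher and 1 lower when adjusted over the list alone. The translesion polymerase gene *POLH* changed by 1.78 ± 0.18, and the damage recognition genes *DDB2* and *XPC* by 1.29 ± 0.19 and 1.16 ± 0.15. The feedback and repair lists had camera adjusted p-values of 6.36e-06 and 1.46e-06, each with an adjusted p = 0.0569 with an estimated correlation. *XPC* shares 30.4% of its exon length with genes on the opposite strand, and whether counting used strand is not stated.

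The steepest rises in NCC, beyond these, came from genes that were nearly silent with DMSO. The cytochrome P450 genes *CYP4F2* and *CYP4F3*, whose products oxidise fatty acids and leukotrienes, rose from 0.267 ± 0.234 to 11.3 ± 2.04 CPM and from 0.366 ± 0.126 to 10.9 ± 2.86 CPM (log2 changes 5.47 ± 0.63 and 4.90 ± 0.50). Both belong to a family of similar sequences between which reads could be split. The stress-response gene *NUPR1* (5.03 ± 0.45), the interleukin-22 receptor gene *IL22RA1* (3.72 ± 0.48), the transcription factor genes *NHLH2* (3.68 ± 0.38) and *GRHL3* (3.68 ± 0.50) and the potassium channel gene *KCNA7* (3.55 ± 0.58) rose as well. So did *KANK3* (3.50 ± 0.31), *FRMPD2* (3.29 ± 0.33) and the TRAIL receptor gene *TNFRSF10A* (3.29 ± 0.39). The cytokine gene *LIF* rose by 2.77 ± 0.21 (adjusted p = 2.12e-05), the ephrin receptor gene *EPHA2* by 1.91 ± 0.28, *GAS7* by 1.77 ± 0.33 and the inhibitory SMAD gene *SMAD7* by 1.54 ± 0.28. Falls were smaller. The adhesion gene *VCAM1* fell from 33.5 ± 5.03 to 10.8 ± 0.277 CPM (log2 change -1.63 ± 0.26). The hedgehog effector *GLI1* changed by -1.50 ± 0.32, the MYC-induced transcription factor gene *TFAP4* by -1.26 ± 0.13 and the Wnt receptor gene *FZD4* by -1.24 ± 0.14. *MAP2K6*, *MAML3*, *TNFAIP6*, *LINC00511*, *ZNF367* and *LIMCH1* fell by log2 values from -1.34 to -1.14. The Wnt modulator *SFRP2* (-1.10 ± 0.14) and the mesenchymal surface markers *PDGFRA* (-1.06 ± 0.23) and *THY1* (-0.95 ± 0.16) fell too. Of 25 semaphorin and ephrin genes, which steer migrating crest cells, 3 rose (*EPHA2*, *PLXNB3* and *EFNB1*) and 1 fell (*SEMA6A*), with 4 and 2 when adjusted over the list alone. The list did not move as a whole (median -0.15, camera upward, adjusted p = 0.795).

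Cell-cycle genes lay lower in NCC with Nutlin-3a, by small amounts. Among 28 G1/S and replication genes 2 fell, *UHRF1*, a reader of hemimethylated DNA (-0.77 ± 0.15), and the histone mRNA binding gene *SLBP* (-0.59 ± 0.14). The thymidylate synthase gene *TYMS* rose by 0.54 ± 0.14. DESeq2 called 8 of the 28 lower and limma-voom 6, and 16 lay lower at an unadjusted p under 0.05. When adjusted over the list alone 13 fell and 1 rose, the list median was -0.43 and camera gave an adjusted p of 7.09e-08 (adjusted p = 0.534 with an estimated correlation). *TYMS* shares 46.6% of its exon length with genes on the opposite strand. Of 32 G2/M genes under the DREAM repressor complex, none passed over all genes in edgeR, 18 lay lower at an unadjusted p under 0.05, 6 fell in DESeq2 and 2 in limma-voom. Adjusted over the list alone 8 of them fell, with a median of -0.47 (camera adjusted p = 7.09e-08; adjusted p = 0.534 with an estimated correlation). Ribosome biogenesis genes had a median of -0.30 with 1 of 28 members falling, over all genes and over the list alone, the rRNA pseudouridylation gene *DKC1* (-0.58 ± 0.13; list adjusted p = 5.36e-05 and adjusted p = 0.534 with an estimated correlation). DNA damage signalling genes (17 members, median -0.28) and fatty acid synthesis genes (12 members, median -0.24) had camera adjusted p-values of 0.00524 and 0.0160, with 2 falling in each when adjusted over the list alone. They had an adjusted p = 0.637 and an adjusted p = 0.408 with an estimated correlation. In these 2 lists no member passed over all genes in edgeR, 6 and 3 lay lower at an unadjusted p under 0.05, DESeq2 called 2 lower in each, and limma-voom 0 and 1.

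Markers of the crest itself moved as well. Of 26 neural crest markers 2 fell, the endothelin receptor gene *EDNRA* (-1.03 ± 0.22) and the craniofacial homeobox gene *ALX1* (-0.84 ± 0.21). DESeq2 called 4 lower and limma-voom 2. Adjusted over the list alone 4 fell, and the median was -0.39 (camera adjusted p = 0.00431; adjusted p = 0.0569 with an estimated correlation). Pluripotency markers, 8 of them measured, had a median of -0.41 and a mean of -0.08. The pair that fell, over all genes and over the list alone, were *LIN28A* (-0.44 ± 0.11), an inhibitor of let-7 processing, and the DNA methyltransferase gene *DNMT3B* (-0.79 ± 0.20). This list had a camera adjusted p of 0.0496 (adjusted p = 0.408 with an estimated correlation, and 0.0506 with the replicate block). Its call was lost without any 1 library except replicate c of NCC with Nutlin-3a (0.0526 to 0.187). Immediate genes of the serum response rose in 4 of 20 cases, 5 higher and 1 lower when adjusted over the list alone: *FOSL1* (2.89 ± 0.54), *EGR1* (2.70 ± 0.43), *ATF3* (1.49 ± 0.29) and *IER3* (1.04 ± 0.15). That list's camera adjusted p of 0.0420 became an adjusted p = 0.698 with an estimated correlation, 0.0539 with the replicate block and 0.0505 to 0.137 without any 1 of 9 libraries. Among 9 cardiac and skeletal muscle markers the cardiac homeobox gene *NKX2-5* rose (2.64 ± 0.39, from 0.324 ± 0.0956 to 2.02 ± 0.606 CPM), 1 likewise over the list alone, and the list median was 1.17 (camera adjusted p = 0.00153; adjusted p = 0.287 with an estimated correlation). Smooth muscle contractile genes did not pass, with a median of -0.08, a mean of 0.01 and an upward camera test (adjusted p = 0.921). Matrix genes did not pass either (median -0.08, camera upward, adjusted p = 0.989), although their adjusted p ran from 0.0419 to 0.982 with 1 library left out. None of the 26 and 30 members passed in edgeR over all genes or over the list alone, 2 and 1 lay higher at an unadjusted p under 0.05, DESeq2 called 1 and 0 higher, and limma-voom none.

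Both the number of NCC calls and the individual weaker calls depended on the libraries. With the replicate letter as a block 685 genes rose and 659 fell, with a block within each cell type 1124 and 1783, and without a filter on low counts 721 and 453. In an edgeR fit of the 6 NCC libraries alone 804 rose and 569 fell, and DESeq2 called 382 lower with all libraries. Without replicate a of NCC with Nutlin-3a, the library with counts in the most genes, 306 rose and 43 fell. Of the 61 calls at a mean under 1 CPM in NCC 22 stood, and of all 636 NCC calls 347. Without any 1 of the 6 NCC libraries 230 to 354 rose and 30 to 87 fell. Fewer libraries in a group also lower the power, which was not separated from the weight of a single library. Of the 59 called genes named here, 23 lost their call without replicate a of NCC with DMSO (adjusted p up to 0.221 over the libraries left out): *ALX1*, *ATF3*, *DKC1*, *DNMT3B*, *EDNRA*, *EFNB1*, *FOSL1*, *GAS7*, *GLI1*, *LIMCH1*, *LIN28A*, *LINC00511*, *MAML3*, *MAP2K6*, *PDGFRA*, *PLXNB3*, *SEMA6A*, *SLBP*, *SMAD7*, *TNFAIP6*, *TYMS*, *UHRF1* and *ZNF367*.

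The second comparison put the same question to early SMC. *MDM2* rose by 3.12 ± 0.33 on the log2 scale, from 208 ± 52.6 to 1814 ± 169 CPM (n = 3 per group; edgeR adjusted p = 6.87e-04). *CDKN1A*, which was already at 629 ± 222 CPM with DMSO, reached 2839 ± 512 CPM, a log2 change of 2.17 ± 0.39 (adjusted p = 0.0176). Its call was lost without replicate a (adjusted p = 0.121) or b (0.0736) of SMC with DMSO, or replicate c of SMC with Nutlin-3a (0.0690). In total 152 genes rose and 13 fell, of which 119 and 3 changed by more than 2-fold.

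All 5 groups of p53 targets rose in SMC, with the preset and with an estimated correlation. With the replicate block and an estimated correlation together none passed (adjusted p = 0.0789 for arrest, death and metabolism, 0.175 for feedback and 0.130 for repair). Cell-cycle arrest targets rose in 10 of 14 cases, 12 when adjusted over the list alone (median 1.44, or 1.32 with 1 gene that had no counts in a group set to its bound; camera adjusted p = 9.62e-26, and adjusted p = 0.0241 with an estimated correlation). *BTG2* changed by 2.52 ± 0.20, *SESN1* by 1.85 ± 0.17 and *SESN2* by 1.29 ± 0.13. Cell death targets rose in 11 of 18 cases, 14 over the list alone (1.51e-25 and 0.0241 in the same order), among them the death receptor genes *FAS* (1.73 ± 0.28) and *EDA2R* (1.67 ± 0.21), *BBC3* (1.63 ± 0.16) and *TRIAP1* (1.20 ± 0.15). Feedback targets rose in 3 of 10 cases, 5 over the list alone (2.67e-07 and 0.0337), with *TP53INP1* at 1.58 ± 0.20 and *PPM1D* at 1.32 ± 0.15. Repair targets rose in 5 of 10 cases, 7 over the list alone (3.03e-09 and 0.0296): *POLH* changed by 1.45 ± 0.18, *XPC* by 1.11 ± 0.15, *GADD45A* by 0.94 ± 0.15 and the replication clamp gene *PCNA* by 0.72 ± 0.14. Metabolic targets rose in 7 of 17 cases, 9 over the list alone (6.66e-16 and 0.0110), with *FDXR* at 1.88 ± 0.20 and the actin regulator *CYFIP2* at 1.21 ± 0.15.

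Other large rises in SMC included the p53-induced noncoding RNA *PINCR* (0.406 ± 0.188 to 6.42 ± 1.55 CPM, log2 change 3.95 ± 0.48) and the carboxypeptidase gene *CPM* (3.15 ± 0.56), which lies beside *MDM2*. The small GTPase gene *RRAD* (2.80 ± 0.46), *WDR63* (2.73 ± 0.46), *GRHL3* (2.66 ± 0.47), *FRMD5* (2.48 ± 0.30) and *THSD1* (2.43 ± 0.31) rose too. *FP236383.1* passed as well (3.34 ± 0.67), although its 3 libraries spread widely with Nutlin-3a (8.62 ± 9.18 CPM). *LIF* (1.28 ± 0.19), *ATF3* (1.30 ± 0.28) and the ephrin gene *EFNB1* (1.00 ± 0.14) rose as in NCC. The log2 change of 0.80 ± 0.27 of *EPHA2* did not pass (adjusted p = 0.352), but passed with a letter block within each cell type (7.40e-04) and without a filter (6.82e-04). Among the 13 genes that fell were the cell-cycle transcription factor genes *E2F2* (-1.61 ± 0.29) and *E2F1* (-0.95 ± 0.18), the replication licensing gene *CDT1* (a fall of 1.00 ± 0.17), the phosphatase gene *CDC25A* (-0.78 ± 0.14), *UHRF1* (-0.76 ± 0.15) and *ZNF367* (-1.38 ± 0.27). The mitotic genes *FBXO5* (-0.76 ± 0.11) and *HJURP* (-0.76 ± 0.12) fell with them, as did *PAQR4* (-0.95 ± 0.19) and the Wnt target *AXIN2* (-0.88 ± 0.16). Of 28 G1/S and replication genes 5 fell (11 in DESeq2 and 4 in limma-voom), 18 when adjusted over the list alone (median -0.50; camera adjusted p = 7.04e-18, and adjusted p = 0.224 with an estimated correlation). No G2/M gene of the 32 passed over all genes in edgeR, 11 lay lower at an unadjusted p under 0.05, 3 fell in DESeq2 and 0 in limma-voom. Adjusted over the list alone 8 of them fell (median -0.30; 1.20e-11, and adjusted p = 0.319 with an estimated correlation).

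A few further lists passed the camera test in SMC with little movement of single members. BMP targets had a median of -0.48 over 16 members (adjusted p = 0.00429; adjusted p = 0.509 with an estimated correlation), of which none passed over all genes or over the list alone in edgeR, 2 lay lower at an unadjusted p under 0.05, and none passed in DESeq2 or limma-voom. Wnt targets had a median of -0.20 over 18 members (0.0213; adjusted p = 0.236 with an estimated correlation), with *AXIN2* falling over all genes and over the list alone. Neural crest markers (median -0.24, adjusted p = 0.0159), ribosome biogenesis genes (-0.18, 5.24e-04), pluripotency markers (-0.21, 0.0202) and mitochondrial transcripts (0.21, 0.00429) also passed, with an adjusted p = 0.111, 0.511, 0.232 and 0.664 with an estimated correlation. In these 4 lists (26, 28, 8 and 13 members) none passed over all genes in edgeR. At an unadjusted p under 0.05, 1 crest marker lay higher and 2 lower, 3 ribosome biogenesis genes and 1 pluripotency marker lay lower, and no mitochondrial transcript did either. DESeq2 called 1 crest marker higher and 1 pluripotency marker lower, limma-voom none, and over the list alone 1 crest marker rose and 1 pluripotency marker fell. Except for BMP targets, each of these calls was lost without at least 1 library. Without replicate a of SMC with DMSO the adjusted p was 0.0946 for neural crest, 0.0920 for Wnt, 0.210 for pluripotency and 0.758 for mitochondrial transcripts, and without replicate c of SMC with Nutlin-3a it was 0.0680, 0.0941, 0.255 and 0.0672. Without replicate c of SMC with DMSO or b of SMC with Nutlin-3a it was 0.122 and 0.128 for pluripotency and 0.110 and 0.0620 for ribosome biogenesis, and for pluripotency it was also 0.0509 to 0.0599 without any 1 of 4 NCC libraries. Smooth muscle contractile genes did not pass in SMC (median -0.02, adjusted p = 0.909), with none of 26 passing in edgeR, over the list alone, in DESeq2 or in limma-voom, and 0 at an unadjusted p under 0.05.

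The SMC counts were sensitive to the model and to single libraries, whose removal also lowers the power. With the replicate letter as a block 246 genes rose and 36 fell, with a block within each cell type 513 and 269, and without a filter 266 and 46. In an edgeR fit of the 6 SMC libraries alone 56 rose and 0 fell, with 794 genes at an unadjusted p under 0.05, while DESeq2 called 58 lower and limma-voom 11 with all libraries. Without any 1 SMC library 74 to 131 rose and 2 to 41 fell, the lowest without replicate a of SMC with DMSO. Of the 38 called genes named here, 18 then lost their call in at least 1 case (adjusted p up to 0.262): *ATF3*, *AXIN2*, *CDC25A*, *CDKN1A*, *CDT1*, *CPM*, *E2F1*, *E2F2*, *FAS*, *FP236383.1*, *GADD45A*, *GRHL3*, *PAQR4*, *PCNA*, *RRAD*, *UHRF1*, *WDR63* and *ZNF367*. The fit of the SMC libraries alone ended 18 calls, among them those of *FBXO5*, *HJURP*, *XPC* and *EFNB1*, which no left-out library ended.

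Most genes that rose in SMC also rose in NCC. Of the 152 genes that rose in SMC, 136 (89.5%) also rose in NCC, against 3.75 for independent lists (one-sided Fisher's exact test, p = 3.64e-208). Of the 13 that fell, 6 also fell in NCC, against 0.141 (Fisher's exact test, p = 2.40e-09), and no gene rose in one cell type and fell in the other. The shared genes were 136 of the 442 that rose and 6 of the 194 that fell in NCC. Fisher's test takes genes as independent draws, which they are not, so its p-values describe the overlap only. The comparisons share no libraries, but they come from the same fit with a shared estimate of the spread. Across the 17915 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.469 and a Spearman rho of 0.399.

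**Figure D2:**
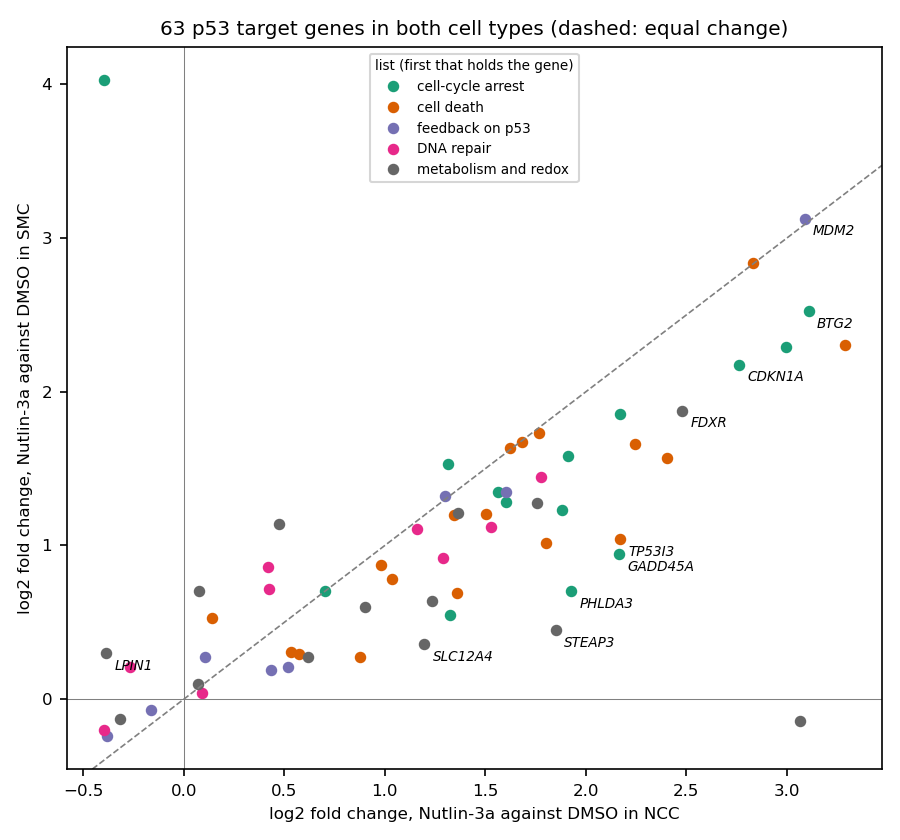
Log2 fold change of 63 p53 target genes with Nutlin-3a in NCC (horizontal axis) and in SMC (vertical axis), coloured by the list that holds each gene; the dashed line marks equal change. Of the 63 points 43 lie below the line.

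How far the response differed between the cell types was tested as the difference of the log2 changes, SMC minus NCC. *MDM2* differed by 0.04 ± 0.43 and *CDKN1A* by -0.59 ± 0.53, both with an edgeR adjusted p of 1.00. No gene passed in the edgeR fit without a block, where 742 genes had an unadjusted p under 0.05 against 896 by chance, or in limma-voom, where 731 did; DESeq2 called 5 genes higher and 23 lower. In edgeR the letter block called 4 and 5, a letter block within each cell type 118 and 103, and no filter 19 and 45. At an unadjusted p under 0.05 lay 1294 genes with the letter block and 2182 with the block within each cell type. Both counts exceed the 896 by chance. Simulated 2-fold differences were called in 10.6% of cases. As groups, p53 targets rose less in SMC. The medians of the difference were -0.46 for arrest (camera adjusted p = 8.90e-06), -0.27 for death (1.30e-04) and -0.32 for metabolism (1.59e-04), with an adjusted p = 0.671, 0.720 and 0.489 with an estimated correlation. Adjusted over the list alone 2, 1 and 4 members changed less and 0, 0 and 1 more. The feedback and repair lists did not pass (adjusted p = 0.674 and 0.373). Over the 63 genes of the 5 lists, the difference was negative for 43 and positive for 20, with a median of -0.26. Adjusted over these 63 alone, 5 genes changed less in SMC: *GADD45A* (difference -1.22 ± 0.21, adjusted p = 0.00435), *PHLDA3*, a repressor of AKT (-1.23 ± 0.25, 0.00897), *TP53I3* (-1.13 ± 0.28, 0.0228), the metalloreductase gene *STEAP3* (-1.40 ± 0.35, 0.0228) and the cotransporter gene *SLC12A4* (-0.84 ± 0.22, 0.0257). The phosphatidate phosphatase gene *LPIN1* differed the other way (0.69 ± 0.20, 0.0417), with a log2 change of -0.39 in NCC and 0.30 in SMC. Over all genes, *GADD45A* passed with the replicate letter as a block (adjusted p = 0.0153, against 0.208 without it). With the block within each cell type it passed (1.57e-04) together with *TP53I3* (0.00103), *PHLDA3* (0.00215), *SLC12A4* (0.00331) and *STEAP3* (0.00704). Without a filter and without a block, *PHLDA3* (6.48e-04), *GADD45A* (6.56e-04), *STEAP3* (0.00235) and *TP53I3* (0.00416) passed over all genes. That fit estimates the spread from genes with few counts as well. Fatty acid synthesis genes had a median difference of 0.30 (8.08e-04; adjusted p = 0.564 with an estimated correlation), with *ACSL3* at 0.56 ± 0.18, *FADS1* at 0.51 ± 0.14 and *ELOVL6* at 0.50 ± 0.15 passing over the list alone. Immediate genes of the serum response (median -0.19, adjusted p = 0.0427), ribosomal protein genes (-0.15, 0.00446) and cardiac and skeletal muscle markers (-1.32, 0.00665) had an adjusted p = 0.923, 0.923 and 0.671 with an estimated correlation. Of the serum genes 1 changed less over the list alone, and of the others none. These calls were lost without at least 1 library: the serum list without any 1 of 8 (0.0519 to 0.596), the muscle list without replicate a of NCC with Nutlin-3a (0.123), and the ribosomal list without any 1 of 4 (0.169 to 0.825, with the direction turned at the last, replicate b of SMC with DMSO).

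The third comparison asked how early SMC and NCC differ without the drug, and the contrast was far larger. Of 17915 genes 4192 were higher in SMC and 4092 lower, of which 2608 and 1803 by more than 2-fold. *CDKN1A* was higher in SMC by 1.80 ± 0.39 on the log2 scale (n = 3 per group; edgeR adjusted p = 0.00236), and *MDM2* was level (0.02 ± 0.30, adjusted p = 0.963). Cardiac alpha-actin, *ACTC1*, which early smooth muscle also expresses, had 5 counts in the NCC libraries and 772 ± 157 CPM in SMC, a ratio of 8181 (95% counting interval 3506 to 25198). The muscle-associated gene *PALMD* had a ratio of 1184 (462 to 4348), *LRRC15* of 890 (159 to 35206) and the RNA-binding regulator of muscle splicing *RBM24* of 770 (138 to 30467). *CCDC85A*, *IL7R*, *SERPINB7* and the adrenergic receptor gene *ADRA1B* had no counts in NCC and were at least 500, 223, 120 and 90.9-fold higher in SMC, with 3 counts over the group as the floor. The small heat shock gene *CRYAB* was higher by 9.13 ± 1.20 and the Wnt antagonist *DKK1* by 9.42 ± 0.74. Lower in SMC were *SMOC1* (-8.92 ± 1.08), the lymphatic growth factor gene *VEGFD* (-7.79 ± 0.67), *ISLR2* (-6.73 ± 0.76), *CCDC33* (-6.19 ± 0.87; ratio 79.5, 41.7 to 175) and the crest stem cell marker *NGFR* (-6.08 ± 0.89). Also lower were *PI15* (-5.96 ± 0.65), the homeobox gene *MEOX2* (-5.85 ± 0.67; ratio 64.6, 34.9 to 135), *NPR1* (-5.83 ± 1.00), *ABCA9* (-5.56 ± 0.56) and *ANGPTL1* (-5.46 ± 0.56).

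Genes of the contractile apparatus and of the matrix were higher in SMC. Of 26 smooth muscle contractile genes 25 were higher and 1 lower, over all genes and over the list alone (median 2.78; camera adjusted p = 7.10e-10, and adjusted p = 0.289 with an estimated correlation). Examples were the SRF cofactor *TGFB1I1* (3.98 ± 0.26), the actin crosslinker *FLNA* (2.16 ± 0.19, from 1373 ± 218 to 6129 ± 621 CPM), the intermediate filament gene *SYNM* (2.66 ± 0.25) and *PDLIM7* (2.69 ± 0.28). Of 30 extracellular matrix genes 23 were higher and 3 lower, 24 and 3 over the list alone (median 2.74; 5.04e-07, and adjusted p = 0.397 with an estimated correlation). The elastin gene *ELN* went from 2.27 ± 0.556 to 297 ± 26.9 CPM (7.02 ± 0.25), *COL6A2* was higher by 2.93 ± 0.25 and *COL6A1* by 2.00 ± 0.16, while the proteoglycan gene *LUM* was lower by -3.25 ± 0.25. Pericyte and fibroblast markers were higher in 10 of 16 cases and lower in 3, 10 and 4 over the list alone (median 1.28; 0.00371, and adjusted p = 0.250 with an estimated correlation), with *HES1* at 3.03 ± 0.31, *CSPG4* at 2.67 ± 0.29 and *NOTCH3* at 1.48 ± 0.17. Cardiac and skeletal muscle markers were higher in 6 of 9 cases and lower in 1, over all genes and over the list alone (median 2.86; 0.0375, and adjusted p = 0.397 with an estimated correlation), mostly at low levels: *TNNT1* reached 0.778 ± 0.437 CPM (ratio 40.0, 6.76 to 1621) and *ACTA1* 1.33 ± 0.231 CPM (9.92, 4.56 to 25.6). That call was lost without replicate c of SMC with DMSO (0.0534) or of SMC with Nutlin-3a (0.0664).

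**Figure D3:**
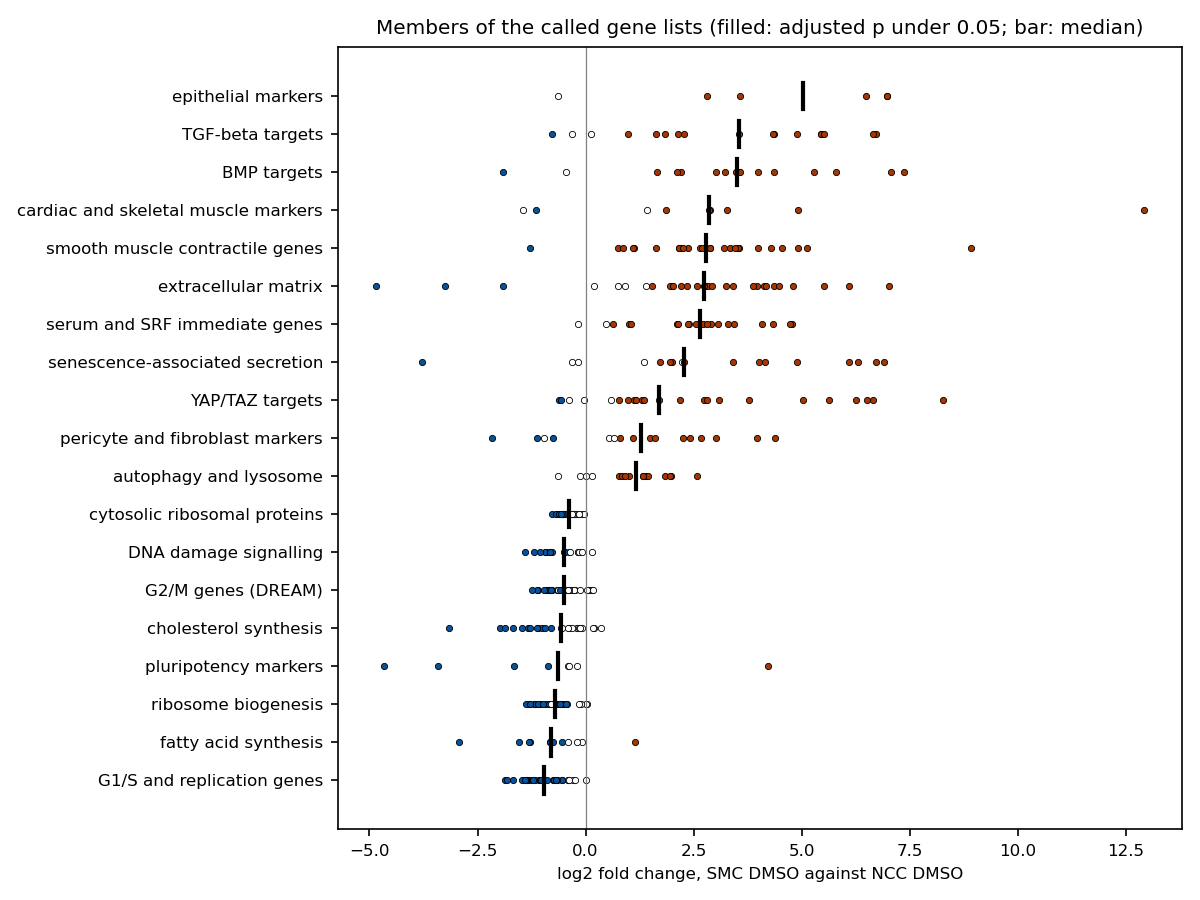
Log2 fold change between SMC and NCC, both with DMSO, of each measured member of the 19 gene lists that passed camera at an adjusted p under 0.05. Filled points passed the edgeR test and bars mark the list medians, which run from 5.03 for epithelial markers to -0.96 for G1/S and replication genes.

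Targets of several signalling routes were higher in SMC. Of 17 TGF-beta targets 14 were higher and 1 lower (median 3.54; camera adjusted p = 3.78e-07, and adjusted p = 0.250 with an estimated correlation), among them the latent TGF-beta binding gene *LTBP2* (4.90 ± 0.34), *SMAD7* (4.35 ± 0.29), *JUNB* (4.32 ± 0.21) and *PMEPA1* (2.28 ± 0.16). Of 16 BMP targets 14 were higher and 1 lower (median 3.51; 2.34e-07, and adjusted p = 0.250 with an estimated correlation), including the BMP antagonist *NOG* (7.37 ± 0.45; ratio 172, 90.6 to 378), *ID3* (3.48 ± 0.22) and *SMAD9* (3.22 ± 0.23). YAP/TAZ targets were higher in 18 of 23 cases and lower in 2 (median 1.69; 1.77e-05, and adjusted p = 0.397 with an estimated correlation), with *ANKRD1* at 8.26 ± 0.84, *CTGF* at 6.65 ± 0.77, *GADD45B* at 6.51 ± 0.40 and *CYR61* at 5.64 ± 0.57. Immediate genes of the serum response were higher in 17 of 20 cases (median 2.64; 9.19e-09, and adjusted p = 0.250 with an estimated correlation), such as *FOSL2* (4.09 ± 0.40), *JUN* (2.89 ± 0.22) and *ZFP36* (2.80 ± 0.24). In these 4 lists the counts adjusted over the list alone were the same. Wnt targets went both ways, with 5 of 18 higher and 9 lower, over the list alone as well (camera downward, adjusted p = 0.248; median -0.77, mean 0.19). *AXIN2* (-2.06 ± 0.16) and the receptor gene *ROR2* (-1.80 ± 0.12) were lower, and *SFRP2* (2.42 ± 0.15) and *DKK1* higher. FGF/ERK targets split into 5 higher and 7 lower of 18, again over the list alone too (0.403), and the FGF feedback genes *IL17RD* (-2.47 ± 0.17), *ETV1* (-1.63 ± 0.21) and *ETV4* (-1.47 ± 0.15) were among the lower.

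Transcripts of several cell-cycle and biosynthesis genes were lower in SMC. Of 28 G1/S and replication genes 22 were lower, 24 over the list alone (median -0.96; camera adjusted p = 6.11e-08, and adjusted p = 0.397 with an estimated correlation), such as *POLA1* (-1.83 ± 0.15), *MCM2* (-1.36 ± 0.18) and *MCM3* (-1.28 ± 0.15). Of 32 G2/M genes 17 were lower, 18 over the list alone (median -0.51; 6.48e-04, and adjusted p = 0.670 with an estimated correlation), with *MKI67* at -1.24 ± 0.22, *TOP2A* at -1.12 ± 0.23 and *TTK* at -0.97 ± 0.16. DNA damage signalling genes were lower in 10 of 17 cases, over the list alone as well (median -0.49; 0.00108, and adjusted p = 0.397 with an estimated correlation), *BRCA1* by -1.41 ± 0.23 and *CHEK2* by -1.06 ± 0.16. Ribosome biogenesis genes were lower in 23 of 28 cases, 24 over the list alone (median -0.72; 3.78e-07, and adjusted p = 0.295 with an estimated correlation), including *NPM1* (-1.20 ± 0.12) and *NCL* (-1.05 ± 0.13). Cytosolic ribosomal protein genes followed in 14 of 34 cases, over the list alone too (median -0.39; 1.82e-04, and adjusted p = 0.670 with an estimated correlation), with *RPL4* at -0.77 ± 0.14 and *RPLP0* at -0.69 ± 0.17. Cholesterol synthesis genes were lower in 13 of 25 cases, 14 over the list alone (median -0.57; 1.30e-04, and adjusted p = 0.397 with an estimated correlation), with the squalene epoxidase gene *SQLE* at -1.32 ± 0.13. Fatty acid synthesis genes were lower in 8 of 12 cases and higher in 1, over the list alone as well (median -0.79; 6.48e-04, and adjusted p = 0.250 with an estimated correlation), with *ELOVL6* at -2.92 ± 0.12 and *ACACA* at -1.53 ± 0.15.

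Markers of cell state showed what the SMC had kept of the crest. Neural crest markers did not move as a group (7 of 26 higher and 11 lower, 10 and 11 over the list alone; median -0.60, camera adjusted p = 0.641). The cadherin gene *CDH6* (3.87 ± 0.21) and *SNAI2* (2.97 ± 0.24) were higher, while the transcription factor genes *ZIC1* (-4.05 ± 0.26) and *ALX4* (-3.63 ± 0.25) were lower. Pluripotency markers were lower in 4 of 8 cases and higher in 1, over the list alone as well (median -0.64; 0.00879, and adjusted p = 0.250 with an estimated correlation), led by *LIN28A*, which went from 598 ± 38.3 to 23.7 ± 1.15 CPM (-4.66 ± 0.12), and *L1TD1* (-3.40 ± 0.24). Epithelial markers were higher in 5 of 6 cases, over the list alone too (median 5.03; 0.00108, and adjusted p = 0.344 with an estimated correlation), with *KRT8* at 6.97 ± 0.60, *CLDN6* at 6.96 ± 0.73 and *KRT18* at 6.49 ± 0.54. Secreted factors of senescent cells were higher in 12 of 17 cases and lower in 1, over the list alone likewise (median 2.27; 1.29e-04, and adjusted p = 0.145 with an estimated correlation), including *MMP1* (6.29 ± 0.45; ratio 87.1, 37.0 to 270), *PLAU* (4.01 ± 0.60), *PLAUR* (2.27 ± 0.31) and *LIF* (1.94 ± 0.20). Autophagy and lysosome genes were higher in 12 of 16 cases, over the list alone too (median 1.16; 1.27e-04, and adjusted p = 0.258 with an estimated correlation), with *VMP1* at 2.58 ± 0.15, *CTSD* at 1.44 ± 0.19 and *MAP1LC3B* at 1.32 ± 0.16. Of 14 measured p53 targets in arrest 7 were higher and 4 lower in SMC before any drug, over the list alone too (camera upward, adjusted p = 0.230; median 0.68). Their mean of -0.02 rests on 1 gene with no counts in a group. The other p53 lists differed from each other at an unadjusted p under 0.05. Of 18 death targets 6 were higher and 1 lower, while DESeq2 and limma-voom each called 6 higher and 0 lower. Of 17 metabolic targets 6 were higher and 6 lower. Of 10 feedback targets 3 were higher and 5 lower, and of 10 repair targets 1 and 5. Of the targets named above for a smaller response in SMC, *PHLDA3* was higher there with DMSO by 1.94 ± 0.18, *STEAP3* by 1.94 ± 0.25, *GADD45A* by 1.51 ± 0.15 and *TP53I3* by 1.19 ± 0.20, values that share their DMSO libraries with the response.

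Serum, the growth factors and CHIR-99021 differ between the media together with the cell type, so these cannot be told apart here. Several named genes overlap others, among them *PLAU*, *SYNM*, *NGFR*, *MCM2*, *CRYAB*, *KRT18* and *JUNB* on the opposite strand and *CCDC85A*, *CTSD* and *AXIN2* on the same strand, so part of their counts may belong to a neighbour.

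**Figure D4:**
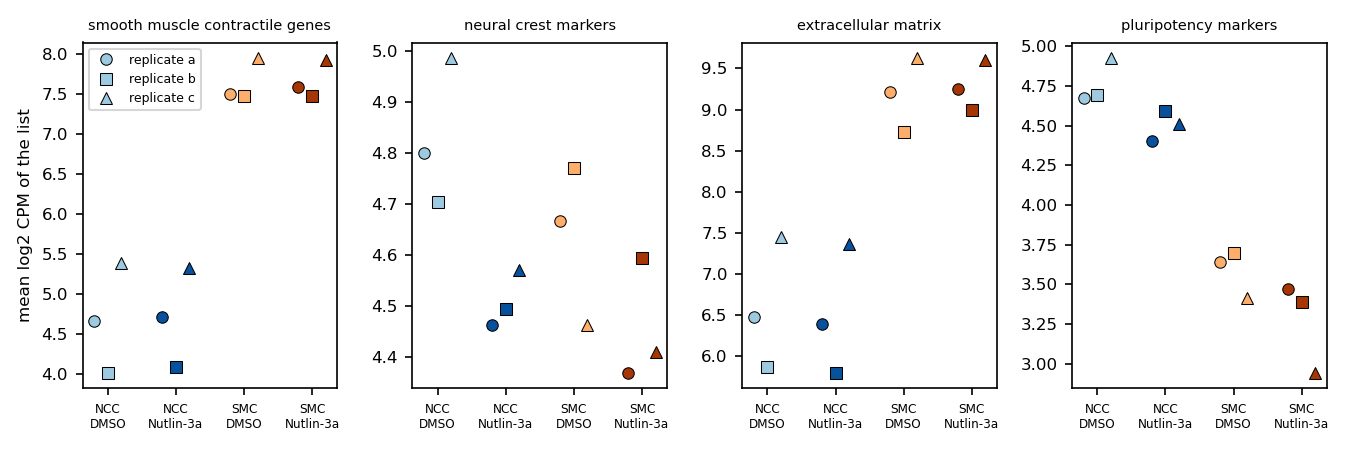
Mean log2 CPM of 4 gene lists in each of the 12 libraries, by group; symbols mark the replicate letter. Smooth muscle contractile genes averaged 4.01 to 5.39 in NCC with DMSO and 7.48 to 7.95 in SMC with DMSO, and replicate c of NCC stood above replicates a and b for that list and for the matrix list.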

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

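Of the tests in this part, those of the library with counts in many more genes, of that library's weight on the p53 response, of the starting level and of the differences within letters were chosen only after the result was seen, while the test of the spread across letters and the relabellings were written down before. The p53 response was flagged because 3 of its lists passed a camera test of the difference between the cell types. The median log2 difference, SMC minus NCC, was -0.46 for arrest, -0.27 for death and -0.32 for metabolic targets, calls of the preset correlation that were lost with an estimated correlation (adjusted p = 0.671, 0.720 and 0.489). Adjusted over the p53 lists alone the single genes were *GADD45A* (-1.22), *PHLDA3* (-1.23), *TP53I3* (-1.13), *SLC12A4* (-0.84), *STEAP3* (-1.40) and, in the other direction, *LPIN1* (0.69).

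The mean rise over the 63 targets overlapped across letters (lowest NCC pair minus highest SMC pair -0.068, with NCC at 1.17, 1.53 and 1.13 and SMC at 0.972, 1.20 and 0.808 for letters a, b and c), but within letters NCC was higher by 0.19, 0.33 and 0.32. The mean of these differences was 0.28 ± 0.04 (SE, n = 3 pairs). The overlap across letters, in the test written down before, is what spread between libraries would give. The differences within letters were examined afterwards and rest on pairs inferred from the data. Between the DMSO groups of the cell types, same-letter correlations were only 0.114, 0.155 and 0.175. Spread between libraries therefore stays open as a cause, although NCC was higher in each letter. Replicate a of NCC with Nutlin-3a was not the cause, since the median difference without it was -0.285 (against -0.258 with it). A higher starting level in SMC is a candidate. Level differences with DMSO in 1 letter and differences of the rise in the other letters had a mean Spearman rho of -0.542 across the 63 genes (-0.528, -0.544 and -0.553). Genes are not independent replicates. The rho was -0.085 across the other 17852 genes, but most of these were not called with the drug. It therefore cannot show whether the relation is particular to p53 targets. The lists did not all start higher in SMC. At an unadjusted edgeR p under 0.05, 7 arrest targets began higher with DMSO and 4 lower. The counts were 6 and 1 for death, 6 and 6 for metabolism, 3 and 5 for feedback, and 1 and 5 for repair. Whether a higher start limits the rise, or whether another property of the cell type sets both, stays open and was not tested.

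Replicate a of NCC with Nutlin-3a was flagged for a signal in data outside the main measurement, since 0.488% of its counts lay in genes too low to test, against at most 0.207% in the other libraries. Genomic DNA in the library is a candidate. Among 26650 autosomal genes nearly silent elsewhere it had 1.08 counts per kb of exon (at most 0.0948 in the others), with a ratio of 1.21 between the highest and the lowest of the 5 commonest gene types, but values from 0.942 to 2.11 per kb across groups of these genes by exon length. RNA of another cell type with few abundant genes of its own would sit in those genes. The 10 genes with the most counts held 1.05% of the counts in genes silent elsewhere. That test sees only genes without counts in the other libraries. It cannot show RNA of another library of this study, or RNA spread over many genes. The treatment did not bring it either, since the other NCC libraries with Nutlin-3a had counts in at most 27690 genes at equal depth, and at this rate the excess would be 1.04% of the library's counts.

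The number of genes called was set against other groupings of the same libraries. In each comparison only 1 of 10 splits of the 6 libraries reached the real number of calls, and that was the real split itself. It called 636 genes in NCC (highest other 1), 165 in SMC (highest other 0) and 8284 between the cell types (highest other 0). With 10 splits a share under 0.05 cannot be reached. Every other split mixes the compared groups, so a true difference widens its spread and leaves few calls. The low counts of the other splits therefore decide nothing. For the difference, where the real labels called 0 genes, all 100 of 100 drawn relabellings call at least as many by construction, so that test decides nothing.

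Further list medians of the difference were flagged by the same test, and all were lost with an estimated correlation (adjusted p = 0.923, 0.564, 0.923 and 0.671): -0.19 for immediate genes of the serum response, 0.30 for fatty acid synthesis, -0.15 for cytosolic ribosomal proteins and -1.32 for cardiac and skeletal muscle markers. The serum, ribosomal and muscle calls were also lost without single libraries (adjusted p up to 0.596, 0.825 and 0.123).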

How the results depend on the processing

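Of these alternatives, the block by column letter, the block by letter within each cell type, RLE factors and left-out libraries for the lists, and the fit without replicate a of NCC with Nutlin-3a for the comparisons that do not use it were chosen only after the data were seen. No paired analysis by replicate number was possible because the count columns carry letters and not numbers, so that planned block was not run. Calls are given as higher and lower, in the order NCC, SMC and difference. Without a filter they were 721 and 453, 266 and 46, and 19 and 45. With the letter as a replicate block they were 685 and 659, 246 and 36, and 4 and 5, and with a replicate block within each cell type 1124 and 1783, 513 and 269, and 118 and 103. A fit of only the 2 groups gave 804 and 569 in NCC and 56 and 0 in SMC, where fewer samples set the spread. DESeq2 called 382 lower in NCC, 58 lower in SMC, and 5 and 23 for the difference. The causes were not tested. All other counts for these comparisons with RLE factors, DESeq2 or limma-voom, and all counts between the cell types, stayed within 1.5 times the reported one. With 1 library of the same cell type left out, NCC calls ran from 230 to 354 higher and 30 to 87 lower and SMC calls from 74 to 131 and 2 to 41. With 1 library of the other cell type left out they ran from 399 to 566 and 130 to 432 in NCC and from 113 to 153 and 7 to 13 in SMC, and the difference stayed at 0 and 0 in edgeR.

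With an estimated correlation 3 of 14 lists kept their call in NCC, 5 of 13 in SMC, 0 of 19 between the cell types and 0 of 7 for the difference, and with the replicate block as well 0, 0, 0 and 0. The block with the preset correlation ended 2 list calls in NCC and none elsewhere, and RLE factors 1, for the difference. In all settings but the estimated correlation 12, 8, 18 and 4 lists kept their calls. The list of cytosolic ribosomal proteins in the difference ran from an adjusted p of 9.05e-07 without replicate a to 0.825 with a reversed direction without replicate b, both of SMC with DMSO. The correlation across genes of the responses, 0.469, was 0.437 without replicate a of NCC with Nutlin-3a and 0.744 among the 659 genes called in either cell type, and DESeq2 shared 193 of its 221 higher and 27 of its 58 lower SMC calls with NCC.

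Of the called genes named here, 36 of 59 in NCC, 16 of 38 in SMC and 107 of 107 between the cell types were called in every setting that tested them, and none reversed. These genes were named for a large change or a small p in the reported fit, which favours their calls. Over all calls fewer stood. Without replicate a of NCC with DMSO, 6456 of 8284 calls between the cell types and 257 of 636 in NCC were shared. In the fit of the SMC libraries alone 54 of 165 were. RLE factors ended the calls of *SLBP* (0.0511), *ALX1* (0.0532), *LIN28A* (0.0541) and *DNMT3B* (0.0580) in NCC and of *ATF3* (0.0666) in SMC. No filter ended *TYMS* (0.0597) and *LIN28A* (0.177) in NCC, limma-voom *FP236383.1* (0.222), *E2F2* (0.0592), *ZNF367* (0.0624) and *AXIN2* (0.0696) in SMC, and the fit of only 2 groups 18 calls in SMC. The letter block added *GADD45A* in the difference and changed no other call of a named gene. The block within each cell type ended none and added *EPHA2* in SMC and 12 of 18 named genes in the difference. Depth was 13801350 to 22721657 counts per library, and genes with counts below the filter were not tested in the reported fit.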

Other observations

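Of the tests in this part, only the letter block within each cell type was chosen after the result was seen, and which values to print was decided with the tables in view. Several genes of other lineages also differed between early SMC and NCC without the drug. In that comparison 46.2% of all 17915 tested genes were called, so single calls here do not mark a lineage. The neuronal cytoskeleton genes *MAP2* (log2 change 3.20 ± 0.26) and *TUBB3* (2.51 ± 0.31) and the intermediate filament gene *NES* (1.52 ± 0.21) were higher in SMC, while the neuronal RNA-binding gene *ELAVL3* (-2.16 ± 0.51) was lower. Of 12 neural markers 3 were higher and 4 lower, over the list alone as well (median -0.43, camera upward, adjusted p = 0.827). *TUBB3* shares 35.8% of its exon length with another gene on the same strand. The receptor tyrosine kinase gene *KIT*, which marks melanocyte precursors, was higher by 3.76 ± 0.64, the endothelial receptor gene *KDR* by 4.51 ± 0.67 (ratio 25.5, 13.6 to 53.8) and the cartilage proteoglycan gene *ACAN* by 5.81 ± 0.38, while the cartilage regulator *SOX9* was lower by -1.67 ± 0.18. Of 6 melanocyte markers 2 were higher, and of 7 endothelial markers 3 were higher and 1 lower, over the list alone too (adjusted p = 0.501 and 0.298). Of 14 cartilage and bone markers 6 were higher and 2 lower, over the list alone too (median -0.10, mean 0.91, adjusted p = 0.641). Of 28 HOX genes, which the most anterior crest lacks, 3 were expressed enough to be tested.

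Guidance and stress genes split. Of 25 semaphorin and ephrin genes 10 were higher and 6 lower in SMC, 10 and 7 over the list alone (adjusted p = 0.679). *SEMA3D* (3.36 ± 0.37) and *EPHA2* (2.15 ± 0.28) were among the higher, and *EPHA4* (-3.88 ± 0.38) and *SEMA4D* (-1.79 ± 0.22) among the lower. The heat shock gene *HSPB1* (3.13 ± 0.25), the glycolytic regulator *PFKFB3* (2.74 ± 0.16), the hypoxia-induced gene *NDRG1* (4.98 ± 0.44) and the interferon-induced gene *ISG15* (4.28 ± 0.49) were higher, whereas the serine synthesis genes *PSAT1* (-1.49 ± 0.17) and *PHGDH* (-0.97 ± 0.13) were lower. The heat shock (3 of 14 higher, 6 lower), hypoxia (3 of 19, 5), interferon (5 of 13, 1) and stress response lists (9 of 25, 6) did not move as groups, with adjusted p-values of 0.360, 0.828, 0.298 and 0.641, and the counts over the list alone were the same.

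Outside the p53 lists too, no difference of the drug response between the cell types passed over all genes in edgeR without a block, with 742 genes at an unadjusted p under 0.05. Values of named genes were, for example, *EGR1* (-2.25 ± 0.56), *FOSL1* (-2.15 ± 0.71), *SMAD7* (-1.67 ± 0.37), *LIF* (-1.49 ± 0.27, adjusted p = 0.268), *EPHA2* (-1.12 ± 0.38), *SOX9* (1.07 ± 0.25) and *SFRP2* (0.93 ± 0.20). In DESeq2 *LIF* (adjusted p = 4.42e-04), *SMAD7* (0.0109), *SFRP2* (0.0141) and *EGR1* (0.0169) passed, as did *GADD45A* (4.42e-04) and *PHLDA3* (0.00340) from the p53 lists. With a letter block within each cell type these 7 genes passed, while *FADS1*, *ELOVL6* and *ACSL3* did not: *SMAD7* (1.57e-04), *EGR1* (0.00103), *FOSL1* (0.00139), *SOX9* (0.00139), *SFRP2* (0.00190), *LIF* (0.00198) and *EPHA2* (0.00212). Without a filter *EGR1* (1.15e-10), *FOSL1* (8.95e-13), *SMAD7* (5.54e-06), *LIF* (8.92e-05), *EPHA2* (0.00384) and *SOX9* (0.00545) passed. That fit estimates the spread from genes with few counts as well and adds no counts to these genes. Its small adjusted p-values are therefore not stronger evidence. *FOSL1*, with the smallest of them, did not pass in the main fit, in DESeq2 or in limma-voom.

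Replicate c had the highest mean of contractile and of matrix genes in each group. The mean log2 CPM of smooth muscle contractile genes was 4.66, 4.01 and 5.39 in replicates a, b and c of NCC with DMSO and 4.71, 4.08 and 5.33 with Nutlin-3a. For matrix genes it was 6.48, 5.86 and 7.45 with DMSO and 6.39, 5.79 and 7.37 with Nutlin-3a. In SMC with DMSO the contractile genes stood at 7.50, 7.48 and 7.95 and the matrix genes at 9.21, 8.73 and 9.63.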
